A study of Neurospora crassa with 14 samples.

How the data were processed

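Messenger RNA of Neurospora crassa mycelium was sequenced in 14 libraries, 2 for each of 7 groups: wild type, strains labelled as deleted for eaf-3, sds3, rlp1 or rlp2, and a marked his-3 strain with 5 ul or 0 ul of Trichostatin A. The word without before one of these gene names stands for this label below. Cultures of 5 ml were shaken for 16 h at 32 °C in minimal medium, RNA was treated with DNase and libraries were made with a stranded mRNA kit, per the labels' protocols. Groups were taken from the genotype or treatment in the labels. The 2 samples of wild type and of each deletion group are different strains, and replicate numbers 1 and 2 were given by the labels to the Trichostatin A samples.

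Only tables of the authors' own comparisons were used, 5 in all, 1 for each deletion against wild type and 1 for Trichostatin A. STAR 2.7.3a, RSEM 1.3.1 and DESeq2 1.24.0 are named by the submitters, per the submitters' processing notes; their roles and settings, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Per the file headers, each deposited table gives for every gene an average, which is a normalized expression signal over libraries, a log2 fold change, a p-value, an FDR and a category score. The average signal was the same in all 4 deletion tables for all 9477 genes, so the authors averaged the same libraries for all 4, and which ones the files do not say. In the Trichostatin A table the deposited log2 fold change was 0 with a mean above 0 for 20 genes, so its average signal covers libraries outside the comparison, and which ones is unknown. The deposited FDR equalled a Benjamini-Hochberg adjustment of the deposited p-values over the genes that have an FDR. The category score of the authors was -1 or 1 exactly where the FDR lay under 0.05 and the absolute log2 fold change over 2. No column held values per library (0 such columns), so library sizes, depth, counts per gene and the spread between 2 libraries could not be read.

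From these tables the standard error of each log2 fold change was computed as the absolute log2 fold change divided by the normal quantile of its deposited p-value, and is called the standard error implied by the deposited p-value. A gene was called higher or lower where the deposited FDR lay under 0.05, with no minimum fold change. No new test of single genes against control was made, except where stated as an alternative. A wild type mean was implied from the average of the deletion set and its 4 fold changes, as if it covered all 10 libraries of that set and all 5 groups had equal weight, which the files do not show. Where this mean was near 0, the fitted fold change depends on how the authors' model treats low values and is no bound. Multigene families and overlapping genes may share reads, and values of such genes are uncertain.

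Of 9552 gene identifiers, 9551 matched a locus tag of a reference gene table (assembly NC12), which was used for symbols, gene order and gene lengths, and 1116 had a symbol. Gene lists were fixed before the data were examined for carotenoid and light response, conidiation, chromatin modifiers, mating and sexual development, quinate cluster, nitrogen, sulfur and phosphorus regulation, and chromosome ends. Lists planned by words in product names could not be formed, because the table holds no product names. They were replaced by lists of symbol stems after the tables were opened and before any list value was computed: antioxidant enzymes, cytosolic ribosomal proteins, glycoside hydrolases and cellulases, heat shock proteins, histones, polyketide synthases, proteasome regulatory particle, respiratory chain, vegetative incompatibility, and genes without a symbol. Planned lists of transporters, proteases, transcription factors, cytochrome P450 genes, tRNA synthetases and mitochondrial ribosomal proteins had no replacement and were not run, and members of other lists that only a product name would give were left out. Lists with at least 5 measured members were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the signed normal quantile of the deposited p-value, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists within a comparison. A correlation estimated from the samples could not be had without values per library. List medians were also ranked among 10000 random lists of the same size matched on the mean in 20 bins.

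Overlaps of calls were tested with Fisher's exact test, two-sided, over genes tested in both tables. Because all deletions share the wild type libraries, 200 simulated sets of unchanged groups against a shared control were drawn, with 1/2 of the smaller squared standard error assigned to the control. Differences between deletions were tested as the difference of the deposited log2 fold changes with both standard errors taken as independent, and Benjamini-Hochberg adjustment over genes. Chromosome ends were the 50 outermost protein-coding genes at each of the 14 ends of 7 linkage groups. Adjacent calls were compared with 10000 permutations of the calls over the gene order. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

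Genes were named by a rule fixed before the data were examined. It took the 4 deleted genes and the 2 genes whose promoters drive the markers; per comparison, among called genes with a mean of at least 20 and without the deleted gene, the 6 largest rises and 4 largest falls; from each list with a set call or 3 or more called members, up to 3 called members with the smallest adjusted p; and the 5 genes called the same way in the most comparisons, ties by the largest smallest change. Genes named outside the rule were chosen after their values were seen: vvd, cry, al-1, frq and sub-1 as light genes where the rule does not name them, the neighbours of NCU05173, NCU07152, NCU09968 and pks-5, the ends of runs of called genes, and list members that moved in opposite directions.

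Alternatives planned before the data were examined were an adjusted p under 0.01, a minimum absolute log2 fold change of 1 or 2, genes with a mean of at least 10, adjustment over every gene with a p-value, Bonferroni adjustment, log2 fold changes centred on their median, other settings of the set test, of the difference test and of the overlaps, and 25 or 100 genes per end. A mean of at least 100 and an odds ratio stratified by 10 bins of the mean were added after seeing the data.

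The steps were tested on simulated data in which 200 genes were changed by known amounts. With the implied standard errors of the sds3 table (9051 genes), 37 of 100 genes changed by 1 on the log2 scale and 85 of 100 changed by 3 were called, with 4 false calls. For the Trichostatin A table (8721 genes) these were 16 and 88 of 100, with 3 false calls, so changes of 1 were often not detectable in that comparison. For rlp1 (8889 genes) 60 and 88 of 100 were called with 7 false calls, for rlp2 (8351 genes) 64 and 97 with 10, and for eaf-3 (9090 genes) 41 and 86 with 8. The test of the difference rlp1 minus sds3 (9208 genes) recovered 160 of 200 genes changed by 3 with 0 false calls, and with the shared covariance removed 170 with 6.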

Results

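Messenger RNA of the filamentous fungus Neurospora crassa was sequenced in 14 libraries that fall into 7 groups of 2. A wild type group and 4 groups with a deletion of sds3, rlp1, rlp2 or eaf-3 made up a set of 10 libraries, and a group treated with 5 ul of Trichostatin A (TSA) and its control with 0 ul made up a set of 4. TSA is an inhibitor of histone deacetylases, and sds3 and eaf-3 are named after yeast subunits of the RPD3 deacetylase complexes. The treated strain and its control were another strain than those of the deletion set. Per the labels this strain was his-3 and carried selection markers driven by the promoters of NCU05173 and NCU07152. All values below are those of the authors' deposited table for each comparison, 5 tables in all, or were computed from them. The tables hold no value per library and no read totals. The depth of each library was therefore unknown here. The sign ± stands for the standard error implied by the deposited p-value. A gene is said to have risen or fallen where its deposited adjusted p lay under 0.05. The standard errors of a gene barely differ between the deletion tables, so these p-values rest on a spread pooled over groups. The samples of a deletion group are different strains, and the labels call those of the TSA set biological replicates.

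The deleted genes were read first, as a check of the labels. In the authors' deposited table of its own comparison eaf-3 (NCU06788) fell by 8.95 ± 1.48 on the log2 scale (adjusted p = 3.71e-08) and rlp2 (NCU02898) fell by 2.95 ± 0.32 (adjusted p = 5.93e-18). The fall was partial for sds3 (NCU01599), at -0.76 ± 0.19 (adjusted p = 0.00059) or 58.9% of the wild type level (45.3% to 76.7%, normal 95% interval). It was also partial for rlp1 (NCU09007), at -1.03 ± 0.33 (adjusted p = 0.0111) or 49.0% (31.5% to 76.4%). In the sds3 and rlp1 tables no other deleted gene fell, and rlp2 rose by 1.19 ± 0.28 in the authors' deposited table for rlp1 (adjusted p = 0.000412). The deleted gene thus gives the direction of the eaf-3 and rlp2 comparisons, while those of sds3 and rlp1, whose genes fell in part, rest more on the label of the group. The partial falls are weighed in the closing section. In the TSA table none of these 4 genes passed the test, with values from -0.37 ± 0.48 for NCU01599 to 0.56 ± 0.42 for NCU02898.

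The genes whose promoters drive the markers were read next. NCU05173 and NCU07152 lie 23 and 10 genes from the ends of linkage groups IV and V. In the authors' deposited table NCU05173 rose in every deletion, by 5.96 ± 0.87 without sds3, 6.20 ± 0.87 without rlp1, 7.17 ± 0.87 without rlp2 and 6.12 ± 0.87 without eaf-3. NCU07152 rose without eaf-3, by 5.07 ± 1.72 (adjusted p = 0.0143). Its values were 0.30 ± 2.16 without sds3 and 2.82 ± 1.79 without rlp1, neither past the test, and 4.68 ± 1.72 without rlp2, where the authors' deposited table gives no adjusted p. Both genes were close to 0 in wild type (implied means of 1.86 for NCU05173 and 0.472 for NCU07152), so their fitted changes are no bounds. Implied wild type means here and below assume that the deposited average covers the 10 libraries of the deletion set. Neither gene is listed in the TSA table used here.

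**Figure D1:**
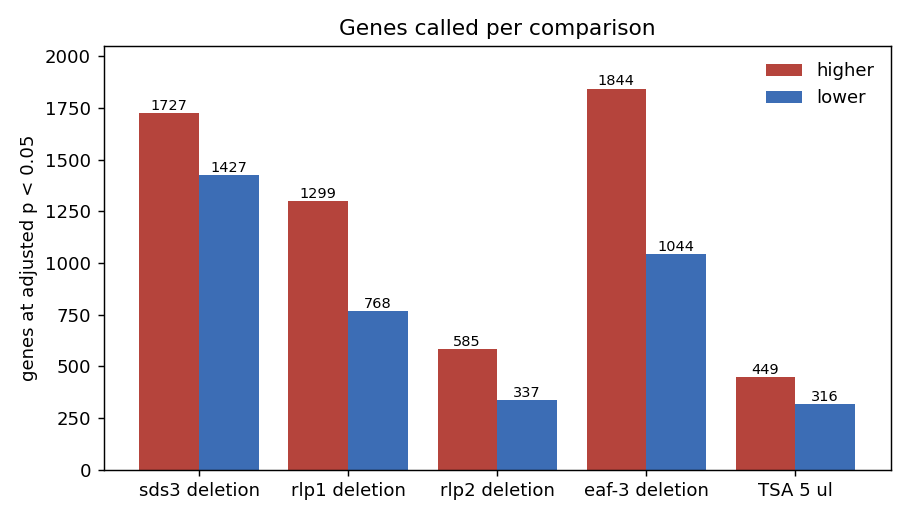
Number of genes (vertical axis) with a deposited adjusted p under 0.05 in each of the 5 comparisons, red bars for higher and blue bars for lower values. The eaf-3 deletion had the most genes called higher (1844), the sds3 deletion the most called lower (1427), and TSA the fewest called lower (316).

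The comparison of the sds3 deletion with wild type asked which genes change when this gene is deleted. Genes of carotenoid synthesis and light response rose together: 9 of 16 rose, 1 fell and 6 did not pass (median log2 fold change 1.23). In the authors' deposited table al-1, which encodes phytoene desaturase, rose by 4.94 ± 0.42 (adjusted p = 3.28e-29), the cryptochrome gene cry by 5.19 ± 0.49 (adjusted p = 7.36e-24) and the carotenoid oxygenase gene cao-2 by 2.52 ± 0.19 (adjusted p = 4.71e-36). The conidiation list, whose members are called conidiation genes here and below, also holds clock-controlled (ccg) genes. Its rises are thus not those of conidiation genes alone. Of its 19 genes 9 rose and none fell (median 1.48), among them csp-1 (3.05 ± 0.29), ccg-13 (4.74 ± 0.64) and con-8 (3.60 ± 0.56) in the authors' deposited table. All 11 cytosolic ribosomal protein genes fell (median -1.49), for example crp-15 (-1.58 ± 0.36), po (-1.49 ± 0.36) and un-16 (-1.52 ± 0.38). Adjusted over the list alone, 9 light genes were higher and 1 lower, and 9 conidiation genes were higher.

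Genes of nitrogen, sulfur and phosphorus regulation fell more often than they rose without sds3, 9 against 2 of 18 (median -0.61; 10 against 2 adjusted over the list alone). In the authors' deposited table the sulfate permease gene cys-14 fell by 4.08 ± 0.49 and the sulfur regulator gene cys-3 fell by 1.46 ± 0.19, while pho-3, a phosphatase gene, rose by 3.50 ± 0.44. Of 7 genes of quinate use 5 rose (median 1.15, likewise 5 adjusted over the list alone), including qa-2 (2.00 ± 0.48), qa-4 (2.55 ± 0.73) and qa-3 (1.15 ± 0.36). Of 41 respiratory chain genes 8 fell and 1 rose (median -0.34): the ATP synthase genes atp-2 (-1.02 ± 0.27) and atp-1 (-1.01 ± 0.27) fell, and nde-1, an alternative NADH dehydrogenase gene, rose (2.06 ± 0.29) in the authors' deposited table. These 6 lists passed the set test (adjusted p = 2.76e-08 for light, 0.000195 for conidiation, 2.39e-05 for ribosomal proteins, 0.00161 for nitrogen, sulfur and phosphorus, 0.0498 for quinate and 0.0299 for the respiratory chain). The last 2 did not hold with a preset correlation of 0.05 (adjusted p = 0.109 and 0.178), with the log2 fold change as statistic (0.127 and 0.0915) or with a mean of at least 10 (0.0667 and 0.0503). Among random lists matched on the mean, the quinate median lay only at percentile 94.4 and that of the respiratory chain at 9.27. The medians of light and conidiation lay at percentile 100, of ribosomal proteins at 0, and of nitrogen, sulfur and phosphorus at 0.58.

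Other lists held members that moved without sds3 but did not pass the set test. Of 11 antioxidant genes 3 rose and 3 fell, with the catalase genes cat-2 (2.72 ± 0.31) and cat-1 (2.79 ± 0.55) up and the glutathione transferase gene gst-1 (-1.72 ± 0.30) down in the authors' deposited table (set adjusted p = 0.851). Of 85 glycoside hydrolase and cellulase genes 14 fell and 8 rose, the falls including gh16-1 (-2.76 ± 0.23), gh61-9 (-2.81 ± 0.29) and gh3-5 (-1.80 ± 0.22). The median was 0.14 while the set test pointed down (adjusted p = 0.444). Of 9 histone genes 3 fell and none rose, namely hH1 (-0.94 ± 0.24), hH2A (-0.89 ± 0.25) and hH4-2 (-0.44 ± 0.18) in the authors' deposited table (set adjusted p = 0.0836). Of 20 chromatin modifier genes 5 rose and 1 fell, with cac-2 (0.55 ± 0.16) and cac-3 (0.77 ± 0.24) up and the deacetylase gene hda-2 down (-0.81 ± 0.29). Adjusted over the list alone these were 2 and 1 (set adjusted p = 0.444). Of 11 heat shock genes 4 rose and 5 fell (set adjusted p = 0.733), with hsp78 up (1.15 ± 0.23) and hsp70-2 (-1.55 ± 0.37) and grp78 (-1.15 ± 0.29) down. Of 17 proteasome genes 3 fell and 1 rose, rpt-1 (-0.69 ± 0.20) and rpn-12 (-0.50 ± 0.16) down and rpn-4 up (1.31 ± 0.25) in the authors' deposited table (set adjusted p = 0.0836). This list was formed by symbol stem, so rpn-4 is not shown to be a subunit of the proteasome. Of 19 mating and sexual development genes 3 rose and 3 fell (also adjusted over the list alone), the meiotic genes spo11 (6.09 ± 1.13) and mei-3 (2.34 ± 0.46) up and the perithecial protein gene app down (-4.23 ± 0.64). Their median was 0.33 and the set test pointed down (adjusted p = 0.704).

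Over all genes with an adjusted p in this comparison (9109), 1727 rose and 1427 fell without sds3. After centring of the log2 fold changes on their median these were 1603 and 1557, so the excess of rises depends on the normalization. The authors' own calls, which also ask for an absolute log2 fold change over 2, number 471 and 134. Among genes with a mean of at least 20 the largest rises were fitted for NCU08085 (11.29 ± 1.52), NCU02923, NCU05763, NCU04926, NCU05190 and NCU16600 (all at 9.74 or more) in the authors' deposited table. Each had an implied wild type mean under 1, so that these sizes are no bounds. The largest falls were those of NCU10387 (-5.94 ± 0.63), NCU03639 (-5.45 ± 0.61), NCU09409 (-5.43 ± 0.71) and NCU00265 (-5.38 ± 0.58). The smallest adjusted p-values among genes without a symbol belonged to NCU01812 (6.37 ± 0.40, adjusted p = 1.44e-53) and NCU00798 (-5.10 ± 0.33, adjusted p = 1.42e-51) in the authors' deposited table. Over the alternatives tried the adjusted p ran from 0.00947 to 0.127 for quinate and from 0.00189 to 0.178 for the respiratory chain. A correlation estimated from the libraries could not be computed without values per library.

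Light and conidiation genes rose without rlp1 as well, in a comparison with the same wild type group. Of the 16 carotenoid and light genes 11 rose and 1 fell (median 1.94, set adjusted p = 2.28e-18; likewise 11 and 1 adjusted over the list alone). In the authors' deposited table cry rose by 6.16 ± 0.49 (adjusted p = 1.37e-33), the photoreceptor gene vvd by 5.56 ± 0.40 (adjusted p = 1.35e-40), al-1 by 5.47 ± 0.42 (adjusted p = 1.12e-35) and cao-2 by 2.72 ± 0.19 (adjusted p = 2.79e-42). Of 19 conidiation genes 13 rose and none fell (median 1.90, set adjusted p = 5.23e-08; 14 adjusted over the list alone), including con-8 (4.14 ± 0.56), ccg-9 (3.35 ± 0.42) and csp-1 (2.29 ± 0.29). Ribosomal protein genes fell here too, 3 of 11 with a median of -0.82 (set adjusted p = 0.004), namely ubi::crp-6 (-0.91 ± 0.29), po (-1.07 ± 0.36) and crp-15 (-0.91 ± 0.36) in the authors' deposited table. The 4 deletions share their wild type libraries, so their falls of these genes are not separate evidence. Whether high values in those libraries gave the falls was not tested. For crp-15 the difference rlp1 minus sds3 was 0.67 ± 0.50 and did not pass its test (adjusted p = 0.483). Of the 41 respiratory chain genes 2 rose and 2 fell (median -0.26, set adjusted p = 0.0083, but 0.145 with a preset correlation of 0.05), with the alternative dehydrogenase genes ndi-1 (-1.28 ± 0.32) and nde-2 (-0.90 ± 0.33) down and nde-3 up (0.81 ± 0.22). The respiratory chain median lay at percentile 18.7 among random lists matched on the mean, so it was not unusual for genes of that level.

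Several other lists had called members without rlp1 and no set call. Of 18 nitrogen, sulfur and phosphorus genes 6 rose and 2 fell (also adjusted over the list alone; set adjusted p = 0.293), the phosphorus genes pho-3 (4.34 ± 0.44) and pho-5 (3.97 ± 0.50) and the nitrate reductase gene nit-3 (1.18 ± 0.27) among the rises in the authors' deposited table. Of 85 glycoside hydrolase and cellulase genes 18 rose and 6 fell (median 0.61, set adjusted p = 0.081), with gh18-4 (3.96 ± 0.41), cdh-2 (5.26 ± 0.72) and gh2-1 (2.86 ± 0.43) up. Of 11 antioxidant genes 4 rose and none fell (set adjusted p = 0.081), among them cat-2 (3.34 ± 0.31), gst-2 (0.83 ± 0.24) and gst-3 (0.94 ± 0.30) in the authors' deposited table. Of 6 polyketide synthase genes 3 rose, pks-1 (0.92 ± 0.29), pks-2 (0.86 ± 0.28) and pks-4 (0.78 ± 0.26) (set adjusted p = 0.293). Of 19 mating genes 4 rose and none fell (4 and 1 adjusted over the list alone; set adjusted p = 0.293), including spo11 (7.12 ± 1.13), app (2.83 ± 0.46) and the pheromone receptor gene pre-1 (1.58 ± 0.43). Of 20 chromatin modifier genes 2 rose and 2 fell (set adjusted p = 0.536): the deacetylase genes hda-1 (0.68 ± 0.16) and nst-1 (0.73 ± 0.18) rose, and the histone methyltransferase gene set-2 fell (-0.68 ± 0.23) in the authors' deposited table.

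In all, 1299 genes rose and 768 fell without rlp1 of 8925 with an adjusted p. The authors' calls number 408 and 48. The largest fitted rises were those of NCU07147 (11.94 ± 1.46), NCU08085, NCU05763, NCU04926, per-1 (10.12 ± 0.80) and NCU08079 in the authors' deposited table, and all but per-1 had implied wild type means under 1. Genes without a symbol with the smallest adjusted p-values were NCU05819 (5.83 ± 0.36, adjusted p = 1.32e-54), NCU05176 (7.19 ± 0.49) and NCU00787 (5.28 ± 0.36). The largest falls were those of NCU05122 (-5.73 ± 1.73), NCU00361 (-5.23 ± 1.08), NCU08630 (-4.55 ± 1.59) and NCU00265 (-4.29 ± 0.58) in the authors' deposited table. With an adjusted p under 0.01 the calls were 1288, of which 71.5% were higher, against 62.8% of the main calls. Over the alternatives the adjusted p of the respiratory chain ran from 0.000328 to 0.145.

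The rlp2 deletion was compared in the same way, and again light and conidiation genes rose. Of 16 carotenoid and light genes 8 rose and none fell (median 0.81, set adjusted p = 1.19e-07; 9 and 1 adjusted over the list alone). The photoreceptor gene vvd rose in the authors' deposited table by 2.55 ± 0.40 (adjusted p = 2.57e-08), al-1 by 2.48 ± 0.42 (adjusted p = 3.8e-07) and cao-2 by 1.72 ± 0.19 (adjusted p = 1.77e-16). Of 19 conidiation genes 6 rose and none fell (median 0.58, set adjusted p = 0.00016; 9 adjusted over the list alone), including ccg-13 (3.48 ± 0.64), con-8 (2.80 ± 0.56) and csp-1 (1.44 ± 0.29). None of the 11 ribosomal protein genes passed the test of single genes, but the list lay low as a set (median -0.66, set adjusted p = 0.00564, but 0.0701 with the log2 fold change as statistic). Genes at chromosome ends passed the set test upward (84 of 686 rose and 18 fell, 96 and 23 adjusted over the list alone, median 0.16, set adjusted p = 0.000945, but 0.229 with a preset correlation of 0.05), with NCU05176 (7.09 ± 0.49), NCU10037 (8.99 ± 0.75) and NCU07150 (6.93 ± 0.60) as examples in the authors' deposited table.

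Of the other lists without rlp2, 9 of 85 glycoside hydrolase and cellulase genes rose and none fell (set adjusted p = 0.0982), cdh-2 by 4.91 ± 0.72, gh61-7 by 2.11 ± 0.54 and gh31-1 by 1.32 ± 0.35 in the authors' deposited table. Of 19 mating genes 3 rose (also adjusted over the list alone; set adjusted p = 0.0957), namely app (3.59 ± 0.46), poi-2 (2.14 ± 0.43) and spo11 (5.52 ± 1.13). Among the 18 nitrogen, sulfur and phosphorus genes 2 rose and 2 fell (set adjusted p = 0.887), with pho-3 (3.86 ± 0.44) and pho-5 (1.71 ± 0.51) up and cys-3 down (-0.70 ± 0.19) in the authors' deposited table. In all 585 genes rose and 337 fell of 8374 with an adjusted p. The authors' calls number 171 and 15. The largest fitted rises were those of NCU07147 (13.07 ± 1.46), NCU16906, NCU05190, NCU06902, NCU09418 and NCU06901 in the authors' deposited table. Each had an implied wild type mean under 1. The largest falls were those of NCU12026 (-4.70 ± 1.58), NCU02675 (-3.97 ± 0.79), NCU00361 (-3.04 ± 0.98) and NCU09648 (-3.01 ± 0.59). NCU05819 (5.42 ± 0.36) and NCU01812 (5.45 ± 0.40) had small adjusted p-values among genes without a symbol. Over the alternatives the adjusted p ran from 0.000574 to 0.0701 for the ribosomal proteins and from 0.00044 to 0.229 for the chromosome ends.

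**Figure D2:**
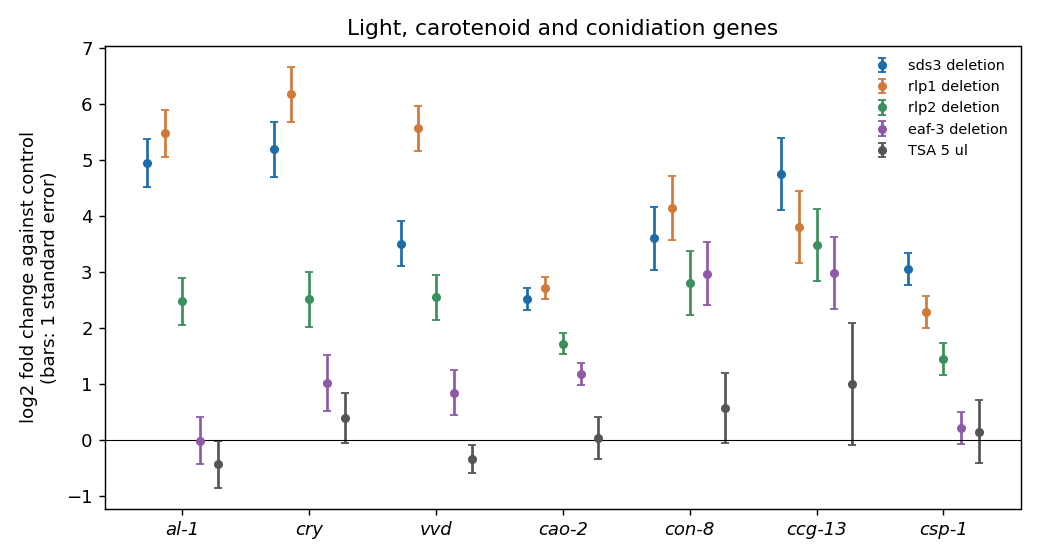
Log2 fold change against the control group (vertical axis, points with bars of 1 standard error implied by the deposited p-value) of 4 light and carotenoid genes and 3 conidiation genes in the 5 comparisons, by colour. The points of al-1 lie at 4.94 without sds3, 5.47 without rlp1, 2.48 without rlp2 and -0.01 without eaf-3.

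The eaf-3 deletion, a gene whose yeast homolog belongs to the small RPD3 complex, was set against the same wild type group. Respiratory chain genes fell, 23 of 41 with 1 rise (median -0.55, set adjusted p = 1.39e-08). Among them in the authors' deposited table the complex I genes nuo24 (-1.64 ± 0.37, adjusted p = 0.000126) and nuo10.4 (-0.97 ± 0.21, adjusted p = 6.17e-05) and the alternative dehydrogenase gene ndi-1 (-1.39 ± 0.32, adjusted p = 0.000135) fell. Of 11 ribosomal protein genes 8 fell (median -1.04, set adjusted p = 0.0017), including po (-1.14 ± 0.36), crp-15 (-1.11 ± 0.36) and un-16 (-1.08 ± 0.38). Mating and sexual development genes rose, 6 of 19 with no fall (median 0.50, set adjusted p = 0.00379, but 0.0755 with the log2 fold change as statistic and 0.123 with ranks; also 6 adjusted over the list alone), with poi-2 (5.70 ± 0.42), the pheromone receptor gene pre-2 (6.23 ± 0.80) and the meiotic silencing gene sms-2 (10.32 ± 1.07, implied wild type mean 0.923) in the authors' deposited table. The mating median lay at percentile 82.7 among random lists matched on the mean, so it was not unusual for genes of that level. The groups hold different strains, whose mating types were not compared here. Changes of mating genes in any deletion, such as pre-1 and pre-2, are therefore not shown to come from the deletion. The medians of the respiratory chain and the ribosomal proteins lay at percentile 0. Genes at chromosome ends rose as a set (199 of 686 higher and 58 lower, 201 and 61 adjusted over the list alone, median 0.48, set adjusted p = 0.0154, but 0.402 with a preset correlation of 0.05), NCU09604 (7.38 ± 0.34, adjusted p = 1.06e-98), NCU09633 (5.17 ± 0.38) and NCU17053 (4.92 ± 0.44) among them.

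The light list did not pass without eaf-3: 4 of 16 genes rose and 1 fell (median 0.16, set adjusted p = 0.645; also 4 and 1 adjusted over the list alone), with cao-2 (1.17 ± 0.19), cao-1 (1.68 ± 0.35) and the phytochrome gene phy-2 (2.76 ± 0.60) higher in the authors' deposited table. Of 19 conidiation genes 7 rose and none fell (median 0.57, set adjusted p = 0.0586; 7 and 1 adjusted over the list alone), including con-8 (2.97 ± 0.56), ccg-1 (2.86 ± 0.58) and ccg-14 (2.55 ± 0.52). Of 85 glycoside hydrolase and cellulase genes 30 rose and 11 fell (set adjusted p = 0.0586), with gh18-8 (6.18 ± 0.55), gh1-1 (4.12 ± 0.48) and gh13-5 (2.05 ± 0.24) up in the authors' deposited table. Of 6 vegetative incompatibility genes 4 rose (set adjusted p = 0.0509), among them pin-c (2.23 ± 0.35), het-6 (1.96 ± 0.33) and un-24 (1.14 ± 0.30). Of 6 polyketide synthase genes 4 rose and 1 fell (set adjusted p = 0.137), with pks-1 (1.65 ± 0.29) and pks-2 (1.41 ± 0.27) up and pks-3 (-1.58 ± 0.28) down. Among 18 nitrogen, sulfur and phosphorus genes 7 rose and 3 fell (also adjusted over the list alone; set adjusted p = 0.296), pho-2 (3.17 ± 0.32), pho-5 (3.46 ± 0.50) and the arylsulfatase gene ars-1 (4.08 ± 0.70) up in the authors' deposited table. Heat shock genes gave 1 rise, hsp78 (0.72 ± 0.23), and 2 falls, hsp88 (-0.58 ± 0.22) and hsp70-2 (-0.93 ± 0.37), of 11 (set adjusted p = 0.578). Chromatin modifier genes gave 2 rises, hda-4 (0.62 ± 0.22) and crf4-1 (0.48 ± 0.18), and 1 fall, set-2 (-0.77 ± 0.23), of 20 (set adjusted p = 0.819).

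Without eaf-3, 1844 genes rose and 1044 fell of 9109. The authors' calls number 988 and 29. NCU01038 (6.83 ± 0.39) and NCU11295 (4.76 ± 0.28) had small adjusted p-values among genes without a symbol in the authors' deposited table. The largest fitted rises were those of NCU05472 (12.12 ± 4.68), NCU06917 (11.99 ± 1.49), NCU05678, NCU07091, the kinase gene stk-35 and NCU11340. Each had an implied wild type mean under 1. The largest falls were those of NCU09968 (-10.08 ± 3.03), NCU09969 (-7.36 ± 2.83), NCU00995 and NCU09648 (-2.87 ± 0.59) in the authors' deposited table. Weakly expressed genes lay high: the median log2 fold change of the 1605 genes with a mean of 10 to 100 exceeded that of the 2471 with a mean of 1000 or more (-0.13) by 1.37. A smaller gradient of the same kind was seen without sds3 (medians 0.44 and -0.13), without rlp1 (0.50 and -0.18), without rlp2 (0.18 and -0.07) and with TSA (0.27 and -0.18). The mean that sorts the genes may itself cover the changed libraries, so a gene barely expressed in the control can enter a bin through its rise. Among genes with a mean of at least 100, a setting chosen after seeing the data, 48.6% of 1905 calls were higher, against 63.9% of the main calls. Over the alternatives the adjusted p ran from 0.00158 to 0.123 for mating genes and from 0.00778 to 0.402 for chromosome ends.

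TSA was used to ask what inhibition of deacetylases does in the strain that carries the markers. No list passed the set test in the TSA table (smallest adjusted p = 0.473), and the light and ribosomal protein lists had no called member (medians -0.30 and -0.21, set adjusted p = 0.97 for each). Single genes did move: in the authors' deposited table NCU05176 rose by 4.18 ± 0.39 (adjusted p = 1.01e-23), NCU04436 by 3.56 ± 0.30 (adjusted p = 2.65e-29) and NCU05069 by 3.55 ± 0.36 (adjusted p = 4.86e-20). Of 17 mating genes 3 rose, the pheromone gene mfa-1 (2.31 ± 0.47), app (3.57 ± 0.81) and pre-2 (2.38 ± 0.55), and 1 fell (3 and 1 also adjusted over the list alone). Their median was -0.35 while the set test pointed up (adjusted p = 0.97). Of 85 glycoside hydrolase and cellulase genes 6 rose and 5 fell (set adjusted p = 0.97), with gh18-4 (3.23 ± 0.57) and gh5-1 (3.21 ± 0.60) up and gh61-9 (-2.58 ± 0.50) down in the authors' deposited table. Of 679 genes at chromosome ends 41 rose and 41 fell (46 and 46 adjusted over the list alone; set adjusted p = 0.977), NCU09484 (3.91 ± 0.43) and NCU05185 (2.01 ± 0.25) being further examples of rises.

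In all 449 genes rose and 316 fell with TSA of 8721 with an adjusted p. The authors' calls number 185 and 49. The largest rises were those of NCU00149 (10.05 ± 3.02), NCU17267 (5.84 ± 1.53), NCU02922 (5.33 ± 1.18), NCU16482 (5.07 ± 0.66), NCU09953 (5.04 ± 1.12) and NCU05764 (4.64 ± 0.76) in the authors' deposited table. The largest falls were those of NCU05319 (-4.99 ± 0.82), NCU00265 (-4.75 ± 0.71), NCU06650 (-4.40 ± 1.16) and the polyketide synthase gene pks-5 (-3.86 ± 1.02). With an adjusted p under 0.01 the number of calls dropped from 765 to 425, and after centring 521 genes were higher and 259 lower.

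Some genes moved the same way in all 5 tables: 43 rose in each and 7 fell in each. By the smallest change over the tables the first 5 were NCU17186, NCU05176, NCU09416, NCU05004 and NCU07144, and all of these rose. Their implied wild type means were low (0.930, 7.92, 3.25, 0.462 and 1.82 in this order), and fitted changes from means near 0 are no bounds. The 4 deletion tables share their wild type libraries, which can raise the agreement among them. In the authors' deposited table NCU17186 rose by 8.18 ± 1.13 without sds3, 7.32 ± 1.13 without rlp1, 8.82 ± 1.13 without rlp2, 4.72 ± 1.15 without eaf-3 and 4.62 ± 0.65 with TSA. The gene NCU09416 rose in the authors' deposited table by 6.55 ± 0.63, 6.73 ± 0.62, 7.50 ± 0.62, 3.90 ± 0.64 and 3.71 ± 0.41 in the same order. NCU05176, 25 genes from the end of linkage group IV, rose by 4.01 ± 0.50 without eaf-3, NCU05004 by 3.49 ± 0.82 and NCU07144 by 3.08 ± 0.75 with TSA in the authors' deposited table.

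The comparison among the deletions asked how far their responses overlap. The rlp1 and rlp2 deletions shared 487 genes that rose and 263 that fell, against 89.2 and 30.9 for independent lists of the same lengths and 272 and 128 for equally long lists from simulated unchanged groups set against the same controls. The sds3 and rlp1 deletions shared 771 rises (251 and 594) and 353 falls (123 and 349). The sds3 and rlp2 deletions shared 433 rises (118 and 319) and 139 falls (57.4 and 184). The eaf-3 deletion shared 561 rises with sds3 (350 and 751), 496 with rlp1 (268 and 609) and 297 with rlp2 (118 and 319), and 377, 297 and 146 falls (164, 89.8 and 42.0 for independent lists; 438, 284 and 155 simulated). With lists of the observed lengths, 6 of the 12 overlaps lay above the simulated average, both directions for rlp1 and rlp2 and for sds3 and rlp1, the rises for sds3 and rlp2, and the falls for rlp1 and eaf-3. The other 6, among them 5 of the 6 overlaps with eaf-3, lay below it. No spread of the simulated numbers was kept, so 353 against 349 and 297 against 284 are not shown to differ. The simulated lists rank noise alone, so a number below theirs does not show that no change was shared. At an unadjusted p under 0.05 in both tables, every pair and direction exceeded its simulated number. Examples are 823 against 40.8 for rises of sds3 and eaf-3 and 411 against 37.2 for falls of sds3 and rlp2. That count grows with the number of changed genes in each table, shared or not. All 12 overlaps were above those of independent lists (largest adjusted p = 6.14e-27, two-sided Fisher's exact tests across genes, which are not independent replicates). Across genes the log2 fold changes correlated with Pearson's r of 0.758 for rlp1 and rlp2, 0.711 for sds3 and rlp1, 0.649 for sds3 and rlp2, 0.406 for sds3 and eaf-3, 0.344 for rlp2 and eaf-3 and 0.333 for rlp1 and eaf-3. Simulated unchanged groups gave 0.456 to 0.476. The covariance exceeded the simulated one in every pair, for example 1.20 against 0.190 for sds3 and rlp1 and 0.701 against 0.181 for rlp1 and eaf-3. All deletions were set against the same wild type group, whose 2 libraries cannot be split, so the part that comes from the shared controls was simulated from the standard errors and not measured.

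Genes that differed between deletions were found by testing the difference itself against sds3. The rlp1 value was higher than the sds3 value for 458 genes and lower for 482, the rlp2 value for 319 and 363, and the eaf-3 value for 1067 and 812. In the light list al-1 differed by -4.95 ± 0.60 (adjusted p = 2.84e-14) and cry by -4.17 ± 0.70 (adjusted p = 1.27e-07) for eaf-3 minus sds3. The gene al-1 differed by 0.53 ± 0.59 for rlp1 minus sds3, not past the test (adjusted p = 0.694, a 95% interval from -0.64 to 1.69). Other light genes did differ: vvd by 2.05 ± 0.57 for rlp1 minus sds3 (adjusted p = 0.00754), and for rlp2 minus sds3 al-1 by -2.46 ± 0.60 (adjusted p = 0.00169) and cry by -2.68 ± 0.69 (adjusted p = 0.00399). Each standard error of a difference took the 2 tables as independent, which is conservative under shared controls. With an assumed shared part removed the counts rose to 2428, 2031 and 3480.

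TSA and the deletions have no control libraries in common. Of the genes that rose with TSA, 181 of 448 rose without sds3 (87.3 for independent lists), 181 of 447 without rlp1 (65.5), 90 of 431 without rlp2 (30.1) and 245 of 448 without eaf-3 (88.4). Of 448 rises with TSA 342 were shared with at least 1 deletion (166 for independent lists), and of 316 falls 153 (86.0). Of the genes that fell with TSA, 132 fell without sds3 (51.8), 63 without rlp1 (28.0), 23 without rlp2 (12.8) and 49 without eaf-3 (37.9). Of these 8 overlaps 7 passed Fisher's exact test (two-sided, largest adjusted p among them 0.00624). The falls shared with eaf-3 did not (adjusted p = 0.0525). Examples of shared rises are app (with rlp1 and rlp2) and pre-2 (with rlp1 and eaf-3), and NCU00265 fell with TSA and without sds3, rlp1 and rlp2. Across genes Pearson's r was 0.313 for sds3, 0.299 for rlp1, 0.223 for rlp2 and 0.307 for eaf-3, and Spearman's rho 0.220, 0.212, 0.101 and 0.191.

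Genes near chromosome ends were compared because facultative heterochromatin of this fungus is common there. Among the 50 outermost genes at each of the 14 ends of the 7 linkage groups, 30.5% rose without eaf-3 against 19.5% elsewhere (adjusted p = 5.04e-10, two-sided Fisher's exact test across genes). The shares were 14.5% against 6.43% without rlp2 (adjusted p = 5.04e-10), 23.6% against 18.6% without sds3 (adjusted p = 0.00547) and 18.4% against 14.3% without rlp1 (adjusted p = 0.0102). As a list in the set test the same genes did not pass for sds3 (adjusted p = 0.113) or rlp1 (adjusted p = 0.173). Called genes lay next to each other more often than permuted calls, and Fisher's test, which takes genes as independent, does not account for this. With TSA 6.61% rose against 5.04%, which did not pass (adjusted p = 0.112), and 6.61% fell against 3.40% (adjusted p = 0.000635). Falls were rarer at the ends without sds3 (78 of 652 genes against 15.9% elsewhere, adjusted p = 0.0102). The falls without rlp1 (7.23% against 8.71%), rlp2 (3.10% against 4.09%) and eaf-3 (8.90% against 11.7%) did not pass. The call on falls without sds3 was lost with the 25 outermost genes and with strata of the mean, and that on TSA rises was gained with the 100 outermost (adjusted p = 3.14e-05).

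**Figure D3:**
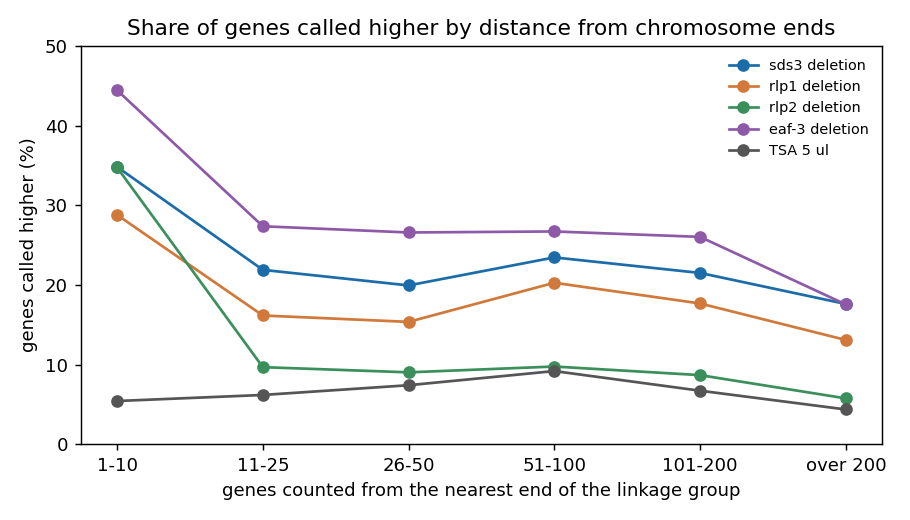
Share of genes called higher (vertical axis, percent) by the position of a gene counted from the nearest end of its linkage group (horizontal axis), one line per comparison. Of the 10 genes nearest each end 44.4% rose without eaf-3, 34.8% without sds3, 34.7% without rlp2, 28.8% without rlp1 and 5.43% with TSA.

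**Figure D4:**
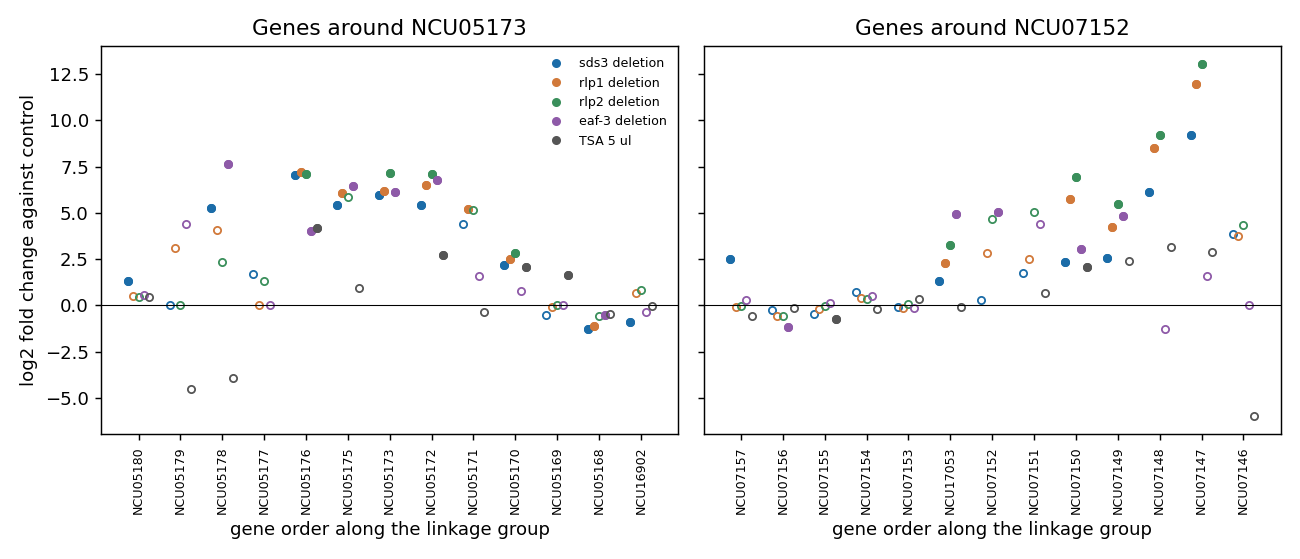
Log2 fold change against the control group (vertical axis) of up to 6 genes on each side of NCU05173 and NCU07152, in gene order, by comparison. Filled points passed an adjusted p under 0.05 and open points did not. NCU07147 lies at 13.07 without rlp2 and NCU05176 at 4.18 with TSA.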

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

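The tests of intact or swapped libraries, of light, of a scaling factor, of low wild type values and of gene length were chosen only after the result was seen, and the dropped test of genomic DNA was written before.

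Some genes moved in opposite directions in different deletions, with a difference that passed its own test: 68 genes for rlp1 against sds3, 35 for rlp2 against sds3 and 175 for eaf-3 against sds3. The perithecial gene app fell without sds3 and rose without rlp1 and rlp2, with differences of 7.06 ± 0.79 (adjusted p = 5.93e-16) and 7.82 ± 0.79 (adjusted p = 6.61e-20) on the log2 scale. The nitrate assimilation genes nit-3 (difference 2.63 ± 0.39) and nit-10 (3.67 ± 0.56) fell without sds3 and rose without rlp1, and NCU08630 did the opposite (-6.53 ± 1.75, adjusted p = 0.00551). Between eaf-3 and sds3 the phosphorus genes pho-2 (4.42 ± 0.49) and pho-4 (3.42 ± 0.67), the sulfur regulator gene cys-3 (2.12 ± 0.27), the incompatibility gene het-6 (2.85 ± 0.49), the sexual development gene asd-1 (5.42 ± 0.70), NCU00798 (6.06 ± 0.43, adjusted p = 1.25e-41) and NCU09604 (9.21 ± 0.68, adjusted p = 7.64e-38) were lower without sds3 and higher without eaf-3. These values are differences of the changes in the authors' deposited table of each comparison, with the standard errors implied by the deposited p-values.

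The first pattern weighed was the partial fall of the deleted gene, to 58.9% of the wild type level for NCU01599 without sds3 and 49.0% for NCU09007 without rlp1. One intact library of the 2 could give such levels. The standard errors barely differ between the deletion tables (at most 1.03 times the median of the other tables for the 2 genes) and so rest on a pooled spread. That spread includes the gene's own 2 libraries, and 1 intact library beside 1 without the gene would widen it. Among the 200 genes nearest in mean the standard errors lay at percentile 15.5 for NCU01599 and 30.5 for NCU09007. By the rule set for this test, standard errors that barely differ between tables make the comparison between tables void, so the rule gives no verdict. The percentiles alone argue against 1 intact library for both genes, although how the authors' model shared spread between genes is not known. A swap with another deletion group would lower another deleted gene, and the lowest such value in these tables was -0.25 ± 0.19, for NCU01599 in the rlp1 table. Reads from a part of the gene left in place could do so too, and cannot be told apart because no read positions are in the tables. A culture that mixes nuclei with and without the deletion in both libraries was not tested.

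The second pattern was the rise of light and carotenoid genes without sds3, rlp1 and rlp2. Low values in the shared wild type libraries would raise these genes alike in every deletion, but over the whole list of 16 genes the median difference eaf-3 minus sds3 was -1.24 (quartiles -2.54 and -0.11), and 8 genes were lower and 2 higher past the test of the difference. More light on the cultures of these strains may also raise such genes: of vvd, frq, al-1, cry and sub-1, 3 were called higher without sds3, 4 without rlp1 and 3 without rlp2, and sub-1 in none. Light and genotype cannot be told apart here, because every culture of a group carries the same deletion and the labels give no light conditions. An effect of the deletion itself stays open as a hypothesis.

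The third pattern was the rise of weakly expressed genes without eaf-3. A scaling factor would move genes of every level alike, but the median at a mean of 10 to 100 exceeded that at 1000 or more by 1.37 on the log2 scale, with smaller gradients in the other 4 tables. A rise that comes from low values in the wild type libraries would be absent against another deletion, but over the 1605 genes with a deposited mean of 10 to 100 the median difference eaf-3 minus rlp2 was 1.03 (quartiles 0.07 and 2.76). The average that sets this bin may cover the eaf-3 libraries, so genes high only there can enter it. Of the 1605 genes, 732 were called higher without eaf-3 and 91 without rlp2. The sizes of 1.37 and 1.03 are thus partly set by the filter, and do not measure how far genes weakly expressed in wild type rise. Reads from genomic DNA would raise long genes more. Over the 1605 genes the rank correlation of gene length and change was 0.00491 (95% interval -0.04 to 0.05). This interval lies wholly under the bound set for DNA, so long genes were not seen to rise more in this bin. It did not lie wholly among negative values, as was asked for the opposite outcome, so the test leaves DNA undecided. The bin may also hold genes that entered it through high eaf-3 values. An earlier test, written before, came out against DNA (25.9% of genes with little gain, over the bound of 20%), and no conclusion is drawn from it. It was dropped because it left out noise and rested on implied wild type means. In 200 sets simulated with noise and an equal gain per kb, 13.5% of genes on average and 15.8% at most had little gain. These simulated sets rest on implied wild type means too. A loss of repression without eaf-3 was not tested and stays open as a hypothesis.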

How the results depend on the processing

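The tests with a mean of at least 100 and with strata of the mean were chosen only after the results were seen. No paired analysis was possible because the tables hold no values per sample, although the groups with 0 and 5 ul of TSA share replicate numbers 1 and 2. For the same reason leaving out each replicate, another test, another normalization of counts, a replicate block and a fit of only 2 groups were not run. Depth is unknown, so which genes were too shallow to be called cannot be said.

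The numbers of called genes stayed within 1.5 times the main number in all 5 comparisons with genes of a mean of at least 10, with adjustment over every gene with a p-value and with centred log2 fold changes (medians removed from -0.08 to 0.05). Centring changed the split of sds3 to 1603 higher and 1557 lower and that of TSA to 521 and 259. With an adjusted p under 0.01 they fell to 1288 for rlp1, 535 for rlp2, 1846 for eaf-3 and 425 for TSA. An absolute log2 fold change of at least 1 left 1828 for sds3, 1171 for rlp1, 585 for rlp2 and 1814 for eaf-3, and of at least 2 left 605, 456, 186 and 1017, and 234 for TSA. Bonferroni adjustment left 874 for sds3, 526 for rlp1, 226 for rlp2, 730 for eaf-3 and 172 for TSA. These counts fell because the settings are stricter by construction. The eaf-3 number was 1905 at a mean of at least 100, where fewer genes were tested. Removing the shared covariance raised the differences from sds3 to 2428 for rlp1, 2031 for rlp2 and 3480 for eaf-3, by construction of a smaller standard error. All 20 overlaps kept their direction and their side of the threshold under both alternatives.

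Set tests moved across the threshold as follows, with adjusted p given, and the cause was not tested. A preset correlation of 0.05 ended the calls of quinate (0.109) and respiratory chain (0.178) for sds3, respiratory chain for rlp1 (0.145), and chromosome ends for rlp2 (0.229) and eaf-3 (0.402). The log2 fold change as statistic ended quinate (0.127) and respiratory chain (0.0915) for sds3, ribosomal proteins for rlp2 (0.0701) and mating for eaf-3 (0.0755), and it added chromosome ends (0.046) and glycoside hydrolases (0.0471) for rlp1 and genes without a symbol for eaf-3 (0.0232). Ranks ended mating for eaf-3 (0.123) and added histones (0.0234) and proteasome (0.00994) for sds3, genes without a symbol (0.0325) and glycoside hydrolases (0.0402) for rlp1, and conidiation (0.0261), genes without a symbol (0.0261) and glycoside hydrolases (0.0481) for eaf-3. A mean of at least 10 ended quinate (0.0667) and respiratory chain (0.0503) for sds3.

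At chromosome ends the log2 odds ratio of falls for sds3 lost its call with 25 genes per end (-0.47), with a log2 fold change of at least 1 (-0.14) and with strata of the mean (-0.22). With 100 genes per end, falls for rlp1 (-0.39) and eaf-3 (-0.34) and rises for TSA (0.78) passed the test. Values that passed under neither setting changed sign for falls of rlp1, to 0.14 with 25 genes and 0.29 with a log2 fold change of at least 1, and for falls of rlp2, to 0.32 with the latter. The rises for all 4 deletions kept their calls under all 4 alternatives. The cause was not tested.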

Other observations

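The tests of adjacency were chosen only after the calls were seen, and these values carry no test of an explanation.

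Genes beside the marker genes moved too. Around NCU05173 the authors' deposited table gave rises of NCU05172 in all 5 comparisons (6.48 without rlp1, 7.12 without rlp2, 5.42 without sds3, 6.79 without eaf-3 and 2.74 with TSA), of NCU05176 in all 5, and of NCU05175 without sds3 (5.40), rlp1 (6.09) and eaf-3 (6.47). Around NCU07152 the gene NCU07150 rose in all 5 (2.36 without sds3, 5.75 without rlp1, 6.93 without rlp2, 3.03 without eaf-3 and 2.06 with TSA), NCU07147 and NCU07148 rose without sds3, rlp1 and rlp2, and NCU17053 rose in the 4 deletions, from 1.32 without sds3 to 4.92 without eaf-3, in the authors' deposited table. The gene NCU07147 had a value of 1.59 without eaf-3, which did not pass.

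Called genes lay next to each other more often than permuted calls did. Without rlp2, 141 neighbouring pairs of genes rose, against 40.7 on average in 10000 permutations, with TSA 71 against 23.1, without eaf-3 694 against 373, without rlp1 321 against 189 and without sds3 494 against 327, each with p = 0.0001, the smallest they can give. The longest run of rises held 17 genes from NCU17062 to NCU04697 on linkage group VI without eaf-3, and 8 genes from NCU05763 to NCU05766 on linkage group VII with TSA. For falls the pairs without rlp2 did not pass the permutation test (19 against 13.5, p = 0.0811).

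With TSA a run of 6 genes from NCU09636 to NCU09641 fell near the end of linkage group IV, and it holds the polyketide synthase gene pks-5 (-3.86) and NCU09640 (-3.76) in the authors' deposited table. Without eaf-3 the other 5 of these genes rose, for example NCU09640 by 5.42 and NCU09636 by 4.82, while pks-5 had a value of 3.35 that did not pass. The difference between TSA and eaf-3 was not tested. Without eaf-3 the neighbours NCU09968 and NCU09969 had values of -10.08 and -7.36 in the authors' deposited table, both past the test, and the genes on either side of them, stk-49 (0.08) and NCU07061 (1.03), did not pass.

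Genes without a symbol, 8360 in the deletion tables, did not pass the set test in any comparison (adjusted p from 0.0509 without eaf-3 to 0.473 with TSA): 1543 rose and 1179 fell without sds3, 1165 rose and 651 fell without rlp1, 526 rose and 291 fell without rlp2, 1676 rose and 852 fell without eaf-3 and 409 rose and 264 fell with TSA. The quinate list had no called member without rlp1, rlp2 or eaf-3, and 1 of 7 rose with TSA.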
